A study of Homo sapiens with 2 samples.

How the data were processed

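The series holds 2 arrays of total RNA from PANC-1, an established human pancreatic carcinoma cell line. Per the labels' protocols, 1 culture received 100 µM rapamycin, a macrolide inhibitor of the mTOR kinase that is used to induce autophagy, and the other was kept in medium alone. The labels conflict at 1 point: the title and the agent of the second array say control, while its source name repeats rapamycin. The group was taken from the agent field, which the title and the treatment protocol bear out, so each direction below rests on that field. RNA was labelled with Cy3 and each sample was hybridised to 1 single-colour array. Both arrays carried the same slide number, so the slide did not differ between the treatments. The array and its place on the slide did, and with 1 array per group they cannot be told apart from treatment. No block could be fitted.

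Per the file headers, the spots were read with Agilent Feature Extraction 12.0.3.1 under the protocol GE1_1200_Jun14, and the deposited scanner values are intensities on a linear scale. The processed signal used here had already been background-subtracted and detrended over the slide by that program, per the file headers. The rapamycin values had been deposited with 3 significant digits, whereas the control values carried up to 7, and this rounding can move a log2 value by at most 0.0072. The authors also deposited a log2 table of 1 value per probe and array, and the submitters' processing notes name limma and Agilent Feature Extraction. Each column of that table correlated across probes at over 0.999 with the log2 signal of its own array (r = 0.99997 for rapamycin and 0.99999 for control) and at 0.99 with the other array, which tied the columns to the arrays. The medians of the authors' columns were 5.90 and 5.90 on the log2 scale; the sorted columns nearly coincided, and how the authors centred and scaled them is not given in the sources used here.

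Each array held 180880 spots, of which 4854 were control spots and 176026 were probes of 60 bases. Of the probes, 88750 carried a circRNA identifier (hsa_circ and a number) and stood for 88373 circRNAs. The other 87276 carried identifiers of the array design only, which cover mRNA and lncRNA together without saying which is which, and they are called linear RNA probes here. None of the 176026 identifiers matched the tables of gene symbols used here (match count 0), and the files do not pair them with gene names. No gene was therefore named from an identifier or a sequence, and probes are given by identifier and sequence. For the same reason the 36 gene lists fixed before the data were examined, the genes to be reported whatever their value, and the separate counts of mRNA and lncRNA genes were not analysed here.

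The log2 processed signal of each array was reduced by that array's 75th percentile over the probes (252 intensity units for rapamycin and 265 for control), and the log2 ratio is rapamycin minus control. A probe was measured when it was well above background on both arrays, had no outlier flag and was not saturated. No probe was saturated (0 on either array). A circRNA with several probes was represented by its brightest one. With 1 array per group there is no test and no p-value: a difference of at least 2-fold was counted by size, and the number of arrays limits the precision. The standard error (SE) given with a single probe is the scanner program's error model for both spots, with a median of 0.21 on the log2 scale. It stands for the reading of a spot as that program models it, and not for the variation between cultures. Over the named probes it lay between 0.204 and 0.209, so it hardly tells their precision apart. The spots of each brighter E1A spike-in control varied by less, 0.05 to 0.07 (SD), and probes with identical sequence had a robust SD of 0.063.

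For probes well above background on 1 array only, again without spots flagged as outliers, the fold is a lower bound. It sets the bright value against the higher of the dim probe's own value and the lowest signal among probes well above background on that array. The probes given by name follow a rule adapted from the rule fixed before the data were examined. They are the 6 highest and 6 lowest ratios among linear RNA probes, and the 3 highest and 3 lowest among circRNA probes, each above the median signal of its class. The earlier rule took 6 and 6 among mRNA genes and 3 and 3 among lncRNA genes, which could not be told apart here. Because linear RNA probes have no gene names here, only 2 identifiers are printed in each direction, and the rest of these probes are summarised.

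Further groupings were chosen after the data were seen. Families are probes linked by an exact stretch of 25 bases, leaving out stretches found in more than 20 probes; families with at least 3 measured probes were used. A family was counted when every probe was at least 1.5-fold apart in 1 direction. Runs are 4 or more consecutive circRNA identifier numbers that were all measured and all at least 1.5-fold apart in 1 direction. A first look had asked for 3 or more numbers at 2-fold, which gave fewer runs, and the rule was widened after that look. The boundary at row 400 was set after the places of the most extreme spots had been seen. Both counts of families and runs were set against 100 shuffles of the ratios within 10 bins of the probes by signal. The shuffles treat every probe as independent, which probes that share sequence are not. Spots with a ratio of at least 16-fold, and the area within 2 rows and 2 columns of them, were treated as possible blemishes.

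The steps were tested on simulated ratios for the same 126706 measured probes, with the noise of each of 10 bins by signal. Simulated 2-fold changes were counted in 50.0% of cases, which follows from their lying at the threshold, and 3-fold changes in 100%. Of the unchanged probes, 0.105% were counted. The simulated noise was normal and taken as even over the slide, which the arrays themselves were not. Its SD in each bin was a robust one, from the median deviation. Probes with identical sequence had an SD of 0.165 per log2 ratio, against a robust SD of 0.063. The 0.105% is therefore not the rate of false counts on these arrays. The alternatives tried were normexp background correction with an offset of 50, quantile normalization, scaling by the median, loess on mean signal with a span of 0.3, no filter on dim probes, probes above the median signal, the median over the probes of a circRNA, and the authors' values. Scaling to the E1A spike-in controls, leaving out blemished areas, using only the rows below 400, and other family stretches were added after the data were seen. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.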

Results

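Total RNA of the PANC-1 line was measured on 1 single-colour array after rapamycin (100 µM) and on 1 array for cells kept in medium alone. The array carries probes for circRNAs, which are closed RNA loops joined by back-splicing, and for linear RNAs. The comparison asks which RNAs differ between cells given rapamycin, which is used to induce autophagy, and cells in medium alone. No marker of autophagy was examined here, since no gene could be named. There were no replicates, so every difference below describes these 2 arrays. The control array's source name repeats rapamycin while its title and agent say control, and the directions follow the agent. Of the 176026 probes, 130592 (74.2%) were well above background on the rapamycin array and 129348 (73.5%) on the control array. On both arrays, 79063 circRNA probes and 47643 linear RNA probes were measured, and their log2 signals correlated at 0.992 across probes, which are not independent replicates.

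Most RNAs had like signals on both arrays. Among circRNA probes, 96.2% differed by less than 1.5-fold, and among linear RNA probes 90.2%. By the 2-fold rule, 216 circRNAs were higher and 188 lower with rapamycin among 78710 measured (0.513%). Here and below, a circRNA stands for the reading of a probe with a circRNA identifier. Such probes can share sequence with linear RNA probes, and the log2 ratios of pairs that did so correlated at 0.67 (3884 pairs). Whether a difference at a circRNA probe came from circular or linear RNA was not tested. Of the linear RNA probes, 534 were higher and 521 lower (2.21%). The larger share among linear RNA probes remained 1.95% when they were weighted to the signal of the circRNA probes. At least 4-fold differences were seen for 20 circRNAs higher and 11 lower, and for 27 linear RNA probes higher and 37 lower. The 2-fold counts depended on the processing: normexp gave 30 circRNAs higher and 23 lower and 65 linear RNA probes higher and 59 lower. Scaling to the E1A spike-in controls turned the balance, to 143 circRNAs higher and 276 lower and 367 linear RNA probes higher and 717 lower.

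**Figure D1:**
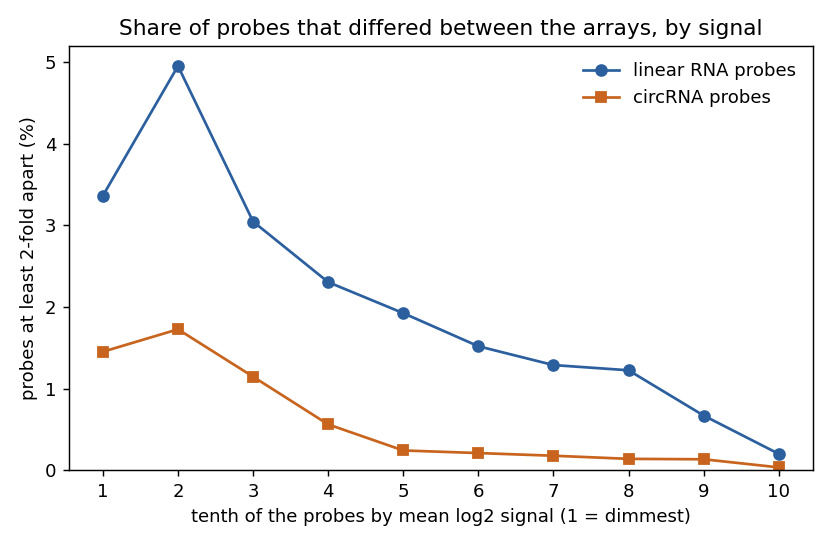
Percent of measured probes at least 2-fold apart between the arrays (vertical axis) in 10 bins of equal size by mean log2 signal (horizontal axis, dimmest first), 1 array per group. Linear RNA probes (circles) lie above circRNA probes (squares) in every bin, from 3.36% against 1.45% in the dimmest to 0.201% against 0.0351% in the brightest.

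These counts depended on where a probe lay on the array, with a boundary at row 400 chosen after the data were seen. In the rows below 400, 48 circRNAs were higher and 8 lower, and 132 linear RNA probes were higher and 57 lower. There 0.189% of circRNA probes and 1.05% of linear RNA probes differed by 2-fold, against 0.707% and 2.92% from row 400 on. The share of circRNA probes (49.9% to 51.1%) was alike from block to block of rows, and the median log2 signal of circRNA probes lay between -0.81 and -0.70. The median of linear RNA probes varied more, from -1.48 in rows 800 to 899 to -1.11 in rows 1000 to 1064. Over the rows below 400 and those from row 400 on it was -1.38 and -1.38. From row 400 on, the differences also went both ways about equally, with 571 probes higher and 644 lower, against 180 and 65 in the rows below 400. The median log2 ratio varied between blocks, from 0.08 in rows 1 to 99 to -0.03 in rows 800 to 899 for linear RNA probes. For circRNA probes it was 0.04 and -0.02 in these blocks. The part of this shift in the direction of the counts was not tested.

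**Figure D2:**
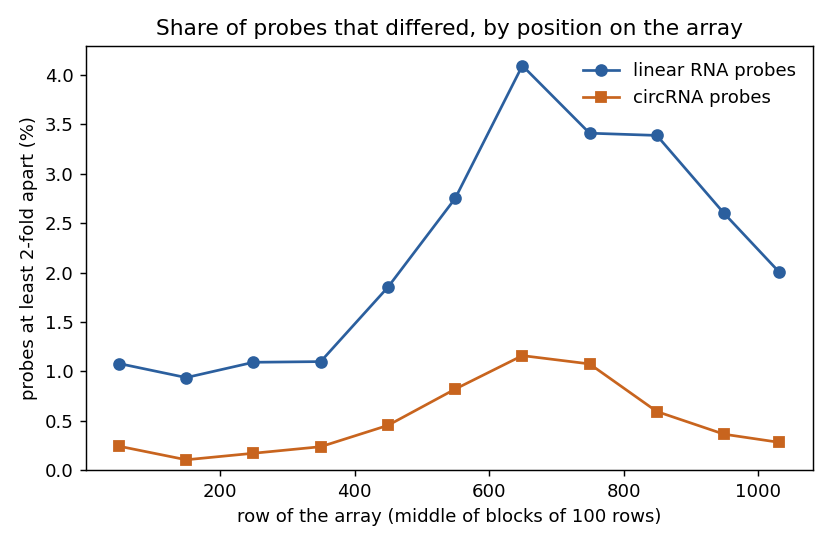
Percent of measured probes at least 2-fold apart between the arrays (vertical axis) by row of the array in blocks of 100 rows (horizontal axis), 1 array per group. The share of linear RNA probes (circles) lies between 0.938% and 1.10% below row 400 and reaches 4.09% in rows 600 to 699, and circRNA probes (squares) reach 1.16% there.

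Among circRNAs above the median signal, hsa_circ_0000123 was 3.78-fold higher with rapamycin. Its log2 ratio was 1.92 (SE 0.20), from normalised log2 signals of 2.87 with rapamycin and 0.95 in the control, for the probe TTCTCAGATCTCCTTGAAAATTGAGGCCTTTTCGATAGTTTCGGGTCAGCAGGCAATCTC. hsa_circ_0013881 was 3.77-fold higher (log2 ratio 1.92, SE 0.21), for the probe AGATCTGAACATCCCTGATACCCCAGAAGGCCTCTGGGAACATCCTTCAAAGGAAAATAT. hsa_circ_0013884 was 3.53-fold higher (log2 ratio 1.82, SE 0.21), for the probe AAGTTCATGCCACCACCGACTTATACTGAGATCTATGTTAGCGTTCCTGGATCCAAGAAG. In the other direction, hsa_circ_0038748 was 3.90-fold lower, from a log2 signal of 1.51 in the control to -0.45 with rapamycin (SE 0.20). hsa_circ_0086169 was 2.76-fold lower (log2 ratio -1.47, SE 0.20), but a probe that shares 25 bases with it had a log2 ratio of -0.02. hsa_circ_0013884, hsa_circ_0038748 and hsa_circ_0086169 lay in the rows with more frequent differences, at rows 777, 619 and 958. The lowest value, -7.82 for hsa_circ_0090398, came from a spot beside other extreme spots, and the probe that shares 25 bases with it had a log2 ratio of 0.07.

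Groups of circRNA probes with neighbouring identifiers were higher together. There were 26 runs of at least 4 consecutive identifiers, all at least 1.5-fold higher with rapamycin, and 2 runs all lower, against at most 2 runs of either kind in 100 shuffles. The shuffles separate overlapping probes, so the excess shows that neighbouring probes moved together and does not count changed RNAs. The longest ran from hsa_circ_0015286 to hsa_circ_0015307, whose 22 probes had a mean log2 ratio of 0.91 ± 0.08 (SD over probes), or 1.87-fold. Their ratios lay between 0.80 and 1.13, and hsa_circ_0015289 had the highest. The 14 probes from hsa_circ_0080242 to hsa_circ_0080255 had a mean of 0.77 ± 0.08. The 13 probes from hsa_circ_0031791 to hsa_circ_0031803 had a mean of 0.85 ± 0.14, and the 13 from hsa_circ_0039377 to hsa_circ_0039389 a mean of 0.77 ± 0.13. Just beyond them, hsa_circ_0031804 had a log2 ratio of -0.21, hsa_circ_0080256 of -0.11 and hsa_circ_0039376 of -0.12, while hsa_circ_0039390 was at 0.26. The numbers beside some of the shorter higher runs also lay on the higher side, up to 0.55. The run with the largest mean, 1.56 ± 0.54, went from hsa_circ_0013881 to hsa_circ_0013885 and held 2 of the circRNAs named above. The longer of the 2 lower runs, from hsa_circ_0040884 to hsa_circ_0040890, had a mean of -0.80 ± 0.06 over 7 probes. Probes within a run can share sequence, up to 52 bases in the longest one, so they are not separate measurements of separate RNAs. Members of the longest run also shared sequence with linear RNA probes that moved alike. The family of hsa_circ_0015294 (5 circRNA probes and 1 linear RNA probe) had a mean of 0.87. That of hsa_circ_0015301 (2 and 1) had a mean of 0.90. Whether these probes read circular or linear RNA cannot be told apart here. With normexp there were 3 higher runs and 1 lower run, and the means of the 4 longest, in the order given, were 0.87, 0.64, 0.56 and 0.54, the last pair below 1.5-fold. Scaling to the spike-in controls turned the balance to 7 higher and 24 lower runs.

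**Figure D3:**
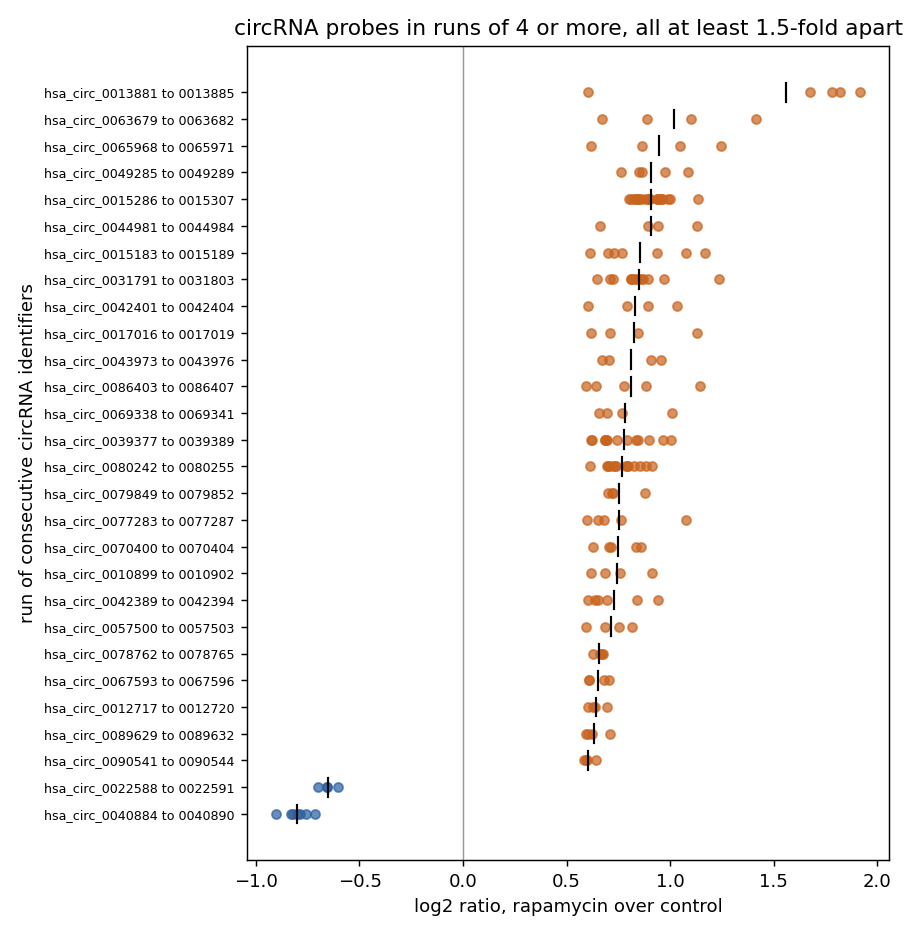
Log2 ratio of rapamycin over control (horizontal axis) for each probe (points) in the 28 runs of 4 or more consecutive circRNA identifiers (vertical axis), with the mean of each run as a bar, 1 array per group. The 26 runs of higher circRNA probes have means from 0.61 to 1.56, and the 2 lower runs have means of -0.65 and -0.80.

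Among linear RNA probes above the median signal, the 2 highest ratios (7.67 and 5.67) came from spots beside other extreme spots. The next were LNCV6_55913, which was 3.97-fold higher with rapamycin (log2 ratio 1.99, SE 0.21), and LNCV6_54673, which was 3.56-fold higher (1.83, SE 0.20). Their probes were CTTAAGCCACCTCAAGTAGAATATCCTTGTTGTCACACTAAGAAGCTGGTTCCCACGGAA and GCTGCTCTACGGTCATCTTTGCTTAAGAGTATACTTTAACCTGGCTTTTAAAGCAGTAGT. The lowest was LNCV6_121012, 5.39-fold lower, from a log2 signal of 9.10 in the control to 6.67 with rapamycin (SE 0.20), for the probe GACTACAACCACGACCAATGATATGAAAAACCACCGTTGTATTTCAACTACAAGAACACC. LNCV6_52699 was 5.03-fold lower (log2 ratio -2.33, SE 0.21), for the probe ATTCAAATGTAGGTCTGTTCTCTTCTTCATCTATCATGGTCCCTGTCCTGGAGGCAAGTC. The other named probes of this class had log2 ratios of 1.79 and 1.79 on the higher side and from -2.20 to -1.88 on the lower side. Of the 12 probes, LNCV6_121012 alone lay in the rows below 400. None of LNCV6_55913, LNCV6_54673, LNCV6_121012 and LNCV6_52699 had a measured probe that shares 25 bases in the same sense.

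Probes that share sequence gave a second reading of some RNAs. Among the 7453 families of at least 3 probes, every probe was at least 1.5-fold higher with rapamycin in 46 families and lower in 8, against at most 3 and 1 in 100 shuffles. The shuffles break the link between probes that share sequence, so this excess does not show how many RNAs changed. The most changed family on the higher side held hsa_circ_0024240 and 2 linear RNA probes, with a mean log2 ratio of 1.62 ± 0.31 (SD over probes), or 3.06-fold. A family of 3 linear RNA probes around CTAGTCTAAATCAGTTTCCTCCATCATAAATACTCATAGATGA had a mean of 1.41 ± 0.09. hsa_circ_0042257 and hsa_circ_0042258, together with a linear RNA probe, shared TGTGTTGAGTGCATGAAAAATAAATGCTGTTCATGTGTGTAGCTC and had a mean of 1.06 ± 0.07. On the lower side, hsa_circ_0004705, hsa_circ_0064425 and hsa_circ_0064426 shared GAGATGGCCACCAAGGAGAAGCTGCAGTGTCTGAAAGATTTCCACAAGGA, with a mean of -1.12 ± 0.08, or 2.17-fold lower. hsa_circ_0069727, hsa_circ_0069728 and hsa_circ_0069729 shared TGGCAGGTTAATAAACTTACTTGGCCTGAC and had a mean of -0.69 ± 0.11. In the family of hsa_circ_0069727 and in that of 3 linear RNA probes, 1 probe each lay beside an extreme spot. Without blemished areas the means of these families were -0.63 and 1.44. With scaling to the spike-in controls, 21 families were higher and 28 lower, and with normexp 14 and 1. With normexp the means of the families given here were 1.05, 0.92 and 0.97 on the higher side, and -0.53, which is less than 1.5-fold, and -0.67 on the lower side.

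Single probes past 2-fold were backed by such partners only in part. Of the circRNA probes at least 2-fold higher, 111 had a partner that shares 25 bases, and the partners' median was at least 1.5-fold higher for 42 of them (37.8%). For circRNA probes at least 2-fold lower this held for 7 of 96 (7.29%). Among linear RNA probes it held for 31 of 46 on the higher side (67.4%) and for 15 of 27 on the lower side (55.6%).

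Some RNAs were well above background on 1 array only, counted here without spots flagged as outliers. With rapamycin only, these were 1113 circRNA probes and 2733 linear RNA probes, and in the control only, 625 and 1982. The bound reached 2-fold for 87 circRNA probes and 353 linear RNA probes on the higher side, and for 101 and 422 on the lower side. The 3 largest bounds among these linear RNA probes ran from at least 15.3-fold to at least 24.8-fold higher, and from at least 19.4-fold to at least 22.1-fold lower. All 6 of these probes lay beside other spots with a ratio of 16-fold or more, so they are not given by identifier.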

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

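Of the tests in this part, the one for less sample signal per spike-in was chosen after the shifts had been seen. The E1A spike-in probes, control spots that the main scaling does not use, read higher on the rapamycin array after scaling, with a median log2 ratio of 0.11 over the 7 brighter of the 9 probes above background. The ratios lay between 0.10 and 0.16, the 60 spots of each probe varied by 0.05 to 0.07 (SD), and the 2 dimmer probes were at 0.11 and 0.07. A lower amount of sample signal per spike-in on the rapamycin array would shift all spike-ins alike, and the 7 ratios lay within a range of 0.0526. It stays open, because 16 other control probes, whose targets are not given in the files, shifted by 0.02 to 0.23, and the 13 brighter ones among them by 0.02 to 0.16. A signal-dependent difference between the arrays stays open as well, because 4 of the 7 probes exceeded the median ratio of array probes of like signal by more than 0.05. No biological explanation was tested.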

How the results depend on the processing

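No paired analysis was possible because each group holds 1 array. The counts kept within 1.5 times their value under quantile normalization, median scaling, loess, the authors' values, the median over the probes of a circRNA and blemished areas left out, except for the lower runs below. Scaling to the E1A probes, the use of the rows below 400 and every alternative for families and runs were chosen after seeing the data. In the order circRNAs higher and lower, linear RNA probes higher and lower, and all probes higher and lower (216, 188, 534, 521, 751 and 709), normexp gave 30, 23, 65, 59, 95 and 82. It started from the mean signal and the background of each spot instead of the processed signal, and added an offset. Which of these lowered the counts was not tested. Without a filter on dim probes the counts were 1018, 853, 3093, 3280, 4115 and 4138, by the probes this adds. Above the median signal they were 32, 30, 110, 63, 143 and 93, and in the rows below 400 they were 48, 8, 132, 57, 180 and 65. Those rows hold 47643 of the 126706 measured probes, but the share past 2-fold was also lower there, 0.514% against 1.54% from row 400 on, and the cause was not tested. The counts above the median signal come from fewer probes. Scaling to the E1A probes lowered every log2 ratio by 0.11, which left 143 circRNAs higher and 276 lower and 367 linear RNA probes higher and 717 lower, and 34.0% of all differing probes were then higher, against 51.4%. Families (46 higher, 8 lower) numbered 14 and 1 with normexp and 21 and 28 with E1A scaling. Higher runs (26) numbered 3 with normexp and 7 with E1A scaling. Lower runs (2) numbered 1 with normexp, 5 with quantile normalization, 4 with median scaling, 4 with loess and 6 with the authors' values. With E1A scaling there were 24. Median scaling lowered every log2 ratio by the same small amount, with the median over probes going from 0.0144 to 0.0130. Its count of lower runs thus turned on probes at the 1.5-fold limit. E1A scaling also lowered every log2 ratio alike. For the other alternatives the cause was not tested. No named probe, family or run changed direction. Of 123 values of the 18 named probes under alternatives, 110 stayed within their SE and 13 moved further, all with normexp. For 3 of the alternatives this outcome was fixed in advance. Median scaling and E1A scaling shift every ratio by the same amount, less than any SE, and leaving out blemished areas keeps a probe's ratio. The count of 110 is therefore no measure of stability. Of 70 values of the 10 named families, 15 moved by more than 1 SD, and of 24 values of the 4 longest runs, 5 did. Taking the percentile over mRNA probes was not run, because mRNA and lncRNA probes are not told apart here, nor were alternatives for gene lists. Keeping saturated probes changed nothing, as there were 0. Signal over background limits the dim probes: 67.8% of the probes past 2-fold lay in the dimmest 3 of 10 bins.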

Other observations

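One pair of opposite changes stood out among RNAs read on both strands. Over 553 pairs of probes in which 1 contains the reverse complement of 25 bases of the other, the log2 ratios were unrelated (r = 0.01 across pairs, which are not independent). In 2 of these pairs both probes were at least 2-fold apart, and in both they went opposite ways. Each pair held LNCV6_121012, at -2.43, with a partner that overlaps its reverse complement by 33 bases. The partners, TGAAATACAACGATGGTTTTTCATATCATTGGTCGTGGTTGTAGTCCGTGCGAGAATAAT and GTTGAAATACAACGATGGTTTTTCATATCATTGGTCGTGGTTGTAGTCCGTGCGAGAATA, had log2 ratios of 1.79 and 1.62. In 0 pairs were both probes at least 2-fold apart in the same direction.

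For 100 circRNAs the array also carried 379 additional probes of 4 kinds. The kind most like the main probe shared a median of 50 bases with it and the other kinds 6 to 11. Their log2 ratios correlated with that of the main probe at 0.53 to 0.58 across 81 to 88 circRNAs, and 1 of these comparisons differed by 2-fold or more. circRNA probes and linear RNA probes that share 25 bases correlated at 0.67 over 3884 pairs, against 0.56 for 73031 pairs of circRNA probes. Consecutive circRNA numbers whose probes share no 12 bases correlated at 0.33 over 47956 pairs, and random pairs at 0.0021.

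Of the tests in the next paragraphs, those for probe sequence, rapamycin, a local blemish and an uneven part of the array were chosen after the results had been seen. Probes that share sequence or a circRNA identifier moved together, with r = 0.57 over 80386 pairs that share 25 bases. Position on the slide is argued against, since pairs at least 100 rows apart correlated at 0.57. A signal-dependent difference between the arrays is argued against as well, since after loess and scaling within 10 bins by signal the correlation was 0.64. The sequence of the probes alone is argued against by probes of the same circRNA with no 12 bases in common, which correlated at 0.54 (95% bootstrap interval over 97 circRNAs from 0.36 to 0.70). Whether rapamycin caused these shared differences, or any other difference between the 2 cultures, cannot be told apart with 1 array of treated cells.

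Spots with a ratio of 16-fold or more numbered 188 (98 brighter on the rapamycin array and 90 on the control array), but only 3 were measured on both arrays, so the ratio is not exact: as a lower bound it reached 16-fold for 31 spots and 4-fold for 155. A change of the transcript is argued against only as far as measured partners go, for the 12 spots that had partners sharing 25 bases. All 12 had a bound of at least 4-fold. The partners' median log2 ratio in the spot's direction was -0.0145, with an SD of 0.28 over the 12 spots and a highest value of 0.40. A partner had to be well above background on both arrays, so partners lost from the dimmer array were left out. This filter favours partners that did not change. The test therefore cannot decide the question for partners left out or for spots without a partner. Spots that lie together are not independent. A local blemish may account for many of the spots, since 47.9% had another such spot within 2 rows and 2 columns, against at most 8.51% in 1000 random placements, and 83.9% of the 31 did. A wider uneven part of the array stays open: from row 400 on, a boundary set from the places of these spots, the share of measured probes past 2-fold was 2.99 times that in the rows below 400 (95% interval 2.61 to 3.43, counting error only). The spots did not follow that share throughout, since the last 3 blocks, from row 800 on, held 5, 5 and 3 of them, while 3.4%, 2.6% and 2.0% of their linear RNA probes were past 2-fold.

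Probes that share 25 bases agreed more often in the upper rows of the array. Of the probes past 2-fold that had a partner sharing 25 bases, the partners' median was at least 1.5-fold the same way for 28 of 46 in the rows below 400 (60.9%) and for 67 of 234 from row 400 on (28.6%). These shares mix position with class and direction. Lower circRNA probes, which were backed least often (7.29%), numbered 8 in the rows below 400 and 180 from row 400 on. Pairs sharing 25 bases correlated at 0.70 when both lay in the rows below 400 and at 0.53 when both lay from row 400 on.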
